A study of Caenorhabditis elegans with 2 samples.

How the data were processed

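The material was whole Caenorhabditis elegans at the second larval stage (L2), of the strain OP75, which carries the unc-119(ed3) mutation and the transgene wgIs75. Per the labels, the strain stably expresses the GATA transcription factor ELT-3 with a C-terminal GFP-FLAG tag, and chromatin was sheared by sonication before immunoprecipitation. The labels define 1 group of 2 biological replicates with mixed sexes, and they do not say how the cultures were separated. No input or mock sample was analysed here, so no background was measured the same way in control samples.

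The authors deposited lists of regions, not reads. For each replicate and for both replicates pooled, the deposited list held 30000 regions called against 1 control alignment, described as peaks together with background. A further short list held the regions that passed the authors' irreproducible discovery rate (IDR) threshold, and the file listing gives it as derived from the pooled list and both replicates' lists. Each list was deposited in the ce10 and in the ce11 genome build. The signal value of a region is the authors' peak caller's own score relative to the control, and its scale is not stated in the deposited files, so it was used only to describe and rank regions within a list. The deposited q-values are given as −log10 of q, and the p-value column was left unset in every list. The aligner, the peak caller and the IDR threshold are not given in the sources used here. No read totals are given either, so the depth of each library is unknown, and confidence intervals cover the counting of regions alone.

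All analyses used the ce11 lists, whose coordinates match the WBcel235 reference. Gene models came from Ensembl release 115, and no coordinate was converted between builds. The following choices were fixed before the data were examined. The 1000 highest regions of each list were taken by signal value, and summits within 150 bp were called shared. A second set of regions, called the replicated high-rank set, held the pooled list's 1000 highest regions that had a shared summit among the 1000 highest of each replicate. Background peaks were the regions of the pooled list below its median rank by signal value, over 500 bp from any of its 5000 highest summits, and numbered 14640. A promoter window ran from 1000 bp upstream to 200 bp downstream of an annotated start of a protein-coding transcript. The GATA site was TGATAA on either strand within 100 bp of the summit. Non-coding RNA genes were tRNA, rRNA, snRNA and snoRNA genes within 200 bp of the summit. Shares were compared by two-sided Fisher's exact test with 95% Wilson confidence intervals. The 21 gene lists were fixed on symbols, and their p-values were adjusted by the Benjamini-Hochberg method against 6917 of 19973 protein-coding genes, those with any pooled-list region in the promoter window. The listed symbol ram-4 was not in the annotation. These p-values treat regions or genes as units and do not measure the spread between replicates.

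The genes named were the nearest protein-coding start for each of the 15 highest IDR regions and for the 10 highest regions of the replicated high-rank set outside the IDR list, up to 4 members of each gene list with a summit in the promoter window, and elt-3 and unc-119 whatever their values. Other names were chosen after their values were seen, and the text says so. Chance overlap between replicates was taken from 1000 seeded draws from replicate 2's whole list. The 100 draws for the replicated high-rank set and the 100 circular shifts of replicate 2's regions along each chromosome were not part of the fixed plan and were added later. Alternatives changed the number of regions (500 and 2000), the summit distance (50 and 300 bp, or reciprocal overlap by 50%), the build, the ranking column, the promoter window (500 to 100 bp and 2000 to 500 bp), the motif and its distance, the background and the replicates required.

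The set construction and tests were tested on simulated data. In 20 simulations of the replicate overlap, 100% of 200 planted shared regions among 1000 were recovered. For the IDR list's GATA test, planting TGATAA in 30% of 33 regions gave a call in 88% of 200 simulations, and planting none gave one in 2%. For the gene lists among IDR regions, 2 planted members among 8 genes were called in 100% of 200 simulations. The planted list was the cuticle collagens with mutant names, with 8 members among the background genes. Every run with 2 planted members gave this list the same counts, so that outcome was also fixed in advance. Larger lists, such as the nuclear hormone receptors with 100, were not simulated, so the power for them is unknown. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.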

Results

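ELT-3 is a GATA factor expressed in the hypodermis, the epithelium that makes the worm's cuticle. Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to locate the tagged protein in whole L2 larvae, in 2 biological replicates of 1 group. The comparisons that this design allows are between the replicates, and between the highest regions and the weaker regions of the same lists. The IDR list held 33 regions in ce11. They were the 33 highest regions of the pooled list, with signal values from 45.4 to 94.8 against a pooled median of 16.4. The authors' q-value was under 0.05 for 15 of the 30000 pooled regions, for 15 of replicate 2's regions and for 0 of replicate 1's, whose lowest q was 0.0698. All signal values and q-values are the authors'.

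The highest region lay between genes on chromosome X, from 11094022 to 11094371 (ce11), with a pooled signal value of 94.8. It ranked 2nd in replicate 1 and 1st in replicate 2, and its nearest protein-coding start, that of W02H3.3, was 3989 bp away. The next region, at 6296399 to 6296748 on X, had a signal value of 92.5 and lay in an intron of mom-1, a gene of the Wnt secretion pathway, 3368 bp upstream of cest-16. Regions of X at nspc-17 (78.3), ZK899.6 (77.7), F55G7.5 (62.9) and Y41G9A.17 (52.3) were also among the 15 highest by pooled signal value. A region at 8036216 to 8036565 lay 4922 bp upstream of xol-1, a switch gene of sex determination, with a signal value of 55.5. On the autosomes, the highest region lay at 3867370 to 3867719 on chromosome III, 309 bp upstream of rpl-3, which encodes a ribosomal protein, and had a signal value of 74.4 and ranks of 4 and 9 in the replicates. A region of chromosome I, from 933302 to 933651, lay 5006 bp upstream of nas-30, an astacin metalloprotease gene, with a signal value of 73.3 and ranks of 3 and 4. The other autosomal regions of this group were nearest to R11A5.6 inside the pck-2 gene (56.3), Y37A1A.2 (56.3), F53F1.4 (56.2), sop-3 (53.0) and egl-27 (51.6). The sop-3 region lay in a coding exon, and the egl-27 region lay in an intron at 6842756 to 6843105 on chromosome II, 527 bp downstream of an annotated start. The gene egl-27 encodes a regulator with a GATA-type zinc finger, and its region ranked 26 in replicate 1 and 1120 in replicate 2.

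The gene of the tagged factor carried 2 IDR regions. The first, at 13937296 to 13937645 on X in an intron of elt-3, had a pooled signal value of 54.3 and 2 TGATAA sites, and it ranked 5 in replicate 2 and 10877 in replicate 1. The second, at 13937872 to 13938221, had a signal value of 46.3 and 0 such sites, and it ranked 6 in replicate 1 and 5010 in replicate 2. The transgene carries elt-3, and the 40 kb around the gene held 27 further pooled-list regions where the median window held 12. At unc-119, the gene mutated in this strain, the IDR list had 0 regions, and the highest pooled region within the gene or 5000 bp upstream had a signal value of 16.8 and ranked 13959.

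**Figure D1:**
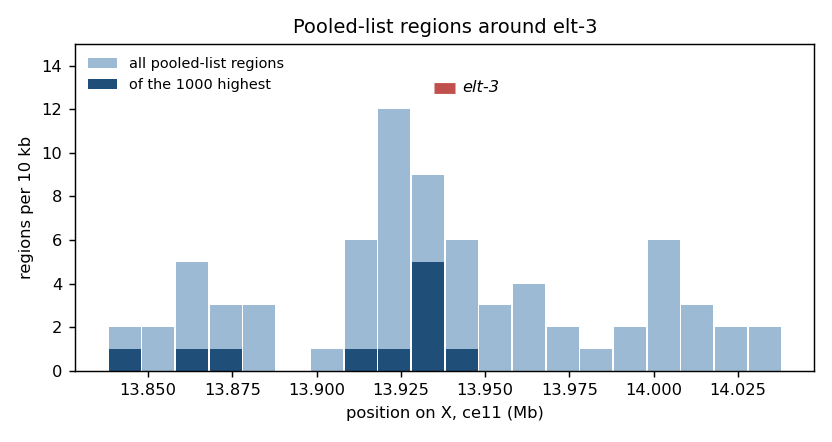
Pooled-list regions per 10 kb (vertical) along X around elt-3 (horizontal, Mb, ce11); pale bars count all regions and dark bars those of the 1000 highest, and the red bar is the elt-3 gene. The highest bins hold 12 and 9 regions, and the bin with 9 holds 5 of the 1000 highest.

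**Figure D2:**
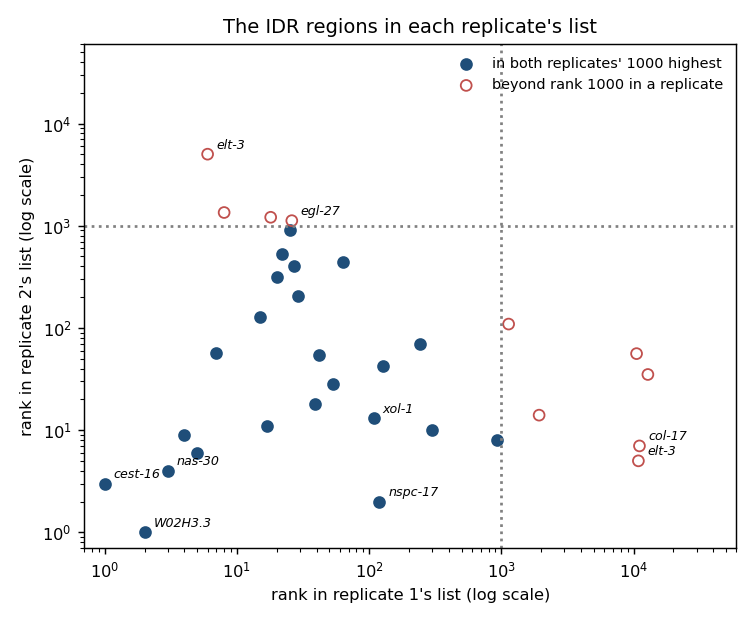
Rank of each of the 33 IDR regions in replicate 1's list (horizontal, log scale) and in replicate 2's list (vertical, log scale), labelled for selected regions by the nearest gene. Filled points are the 23 regions among the 1000 highest of both lists, and open points are the 10 others, with the elt-3 regions at opposite corners.

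Among the 33 IDR regions, 23 lay in the 1000 highest of both replicates (69.7%, 95% Wilson interval 52.7 to 82.6%), 27 in replicate 1's and 29 in replicate 2's. The 100 highest of both replicates held 10 of them, including the regions at W02H3.3, cest-16, rpl-3 and nas-30. By contrast 5 IDR regions ranked beyond 5000 in 1 replicate, 4 of them in replicate 1, among which were the first elt-3 region and, chosen after the values were seen, regions nearest to col-17, egl-30 and inx-13.

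Across the lists, 67 of replicate 1's 1000 highest regions had a summit within 150 bp of one in replicate 2's 1000 highest (6.7%, interval 5.31 to 8.42%). Random draws from replicate 2's list gave a mean of 13.2 and at most 24 in 1000 draws, so the observed overlap was 5.07-fold higher. Over the shared regions Spearman's rho of the signal values was 0.37, which is a value across regions and not across replicates. The share was 18.2% for the 33 highest regions, fell to 10% at 100 and 6.7% at 1000, and rose to 23.5% for all 30000, where shifted positions gave 8.95%. The replicated high-rank set held 68 regions, 45 of them outside the IDR list, where draws gave a mean of 10.2 and at most 18. The 10 highest of those 45 were nearest to irld-18 (signal value 44.8), dlg-1 (44.6), mod-5 (43.9), Y81B9A.1 (43.4), nas-30 (43.4), ZK973.9 (43.0), K07A3.3 (42.8), K02D3.1 (42.8), Y71G12B.3 (41.8) and zfr-1 (41.7). Of these, dlg-1 encodes an adherens junction protein of epithelia and mod-5 a serotonin transporter.

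**Figure D3:**
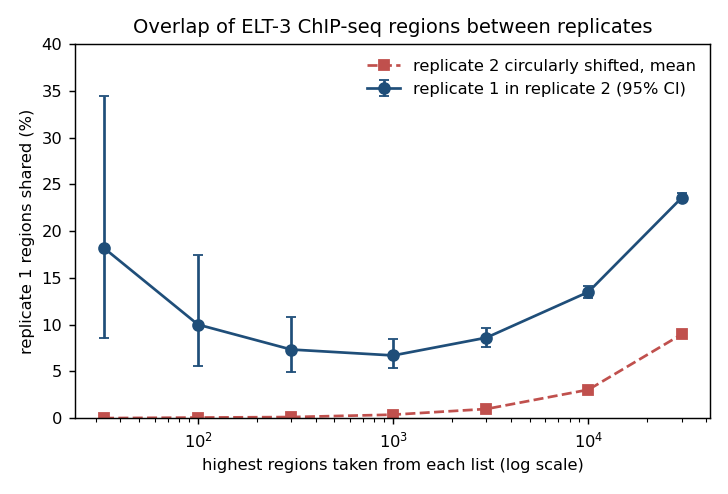
Share of replicate 1's highest regions with a replicate 2 summit within 150 bp (vertical, percent) by the number of regions taken from each list (horizontal, log scale). Blue points carry 95% Wilson intervals, and red squares are the mean of 100 circular shifts; at 1000 regions the values are 6.7% and 0.368%.

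Relative to genes, 15 IDR summits were intergenic, 11 lay in introns, 6 in coding exons and 1 in a 3′ UTR. The median distance to a protein-coding start was 1364 bp, and 13 summits were over 2000 bp away. Promoter windows held 8 of the 33 summits (24.2%, interval 12.8 to 41.0%) against 25.9% of background peaks (odds ratio 0.914, exact p = 1). The genes concerned included nspc-17, rpl-3, R11A5.6 and elt-3, and, named after the values were seen, egl-30, enee-1 and inx-13. In the replicated high-rank set 9 of 68 summits lay in promoter windows (13.2%, interval 7.12 to 23.3%), fewer than in the background (odds ratio 0.436, exact p = 0.0175). That difference was not past the threshold when a single replicate was required (odds ratios 0.887 and 0.938) or with the shorter window (0.494, exact p = 0.157).

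The GATA site TGATAA lay within 100 bp of 8 of the 33 IDR summits (24.2%, interval 12.8 to 41.0%) and of 16.6% of background peaks, a difference that did not pass the test (odds ratio 1.61, exact p = 0.241). The wider motif WGATAR was found at 18 of 33 IDR summits (54.5%) against 34.7% (odds ratio 2.25, exact p = 0.0263), and HGATAR at 22 of 33 (66.7%) against 42.3% (odds ratio 2.72, exact p = 0.00719). Outside the 0.5 Mb bins dense in replicate 1's 1000 highest regions, a limit chosen after the data were seen, 19 IDR summits remained. HGATAR was found at 15 of them (odds ratio 5.11, exact p = 0.0017), WGATAR at 11 (odds ratio 2.58, exact p = 0.0507) and TGATAA at 4 (odds ratio 1.34, exact p = 0.541). These 19 were compared with all background peaks, those in the dense bins included. Of 54 other orders of the bases of TGATAA, 4 had an odds ratio at or above its value in the IDR set. The threshold was passed by 5 of them in either direction. Their median odds ratio was 0.694, below 1. Against background peaks matched on GC content, TGATAA in the IDR set had an odds ratio of 2.03 (exact p = 0.118). IDR regions with TGATAA included those at ZK899.6, nas-30, Y37A1A.2 with 3 sites, elt-3 and egl-27. In the replicated high-rank set 8 of 68 summits had TGATAA (11.8%, odds ratio 0.671, exact p = 0.33). There the other orders had a median odds ratio of 0.690, so the value for TGATAA was close to that of the control. Against the GC-matched background it was 0.792 (exact p = 0.722). Neither WGATAR (25 of 68, odds ratio 1.09, exact p = 0.704) nor HGATAR (31 of 68, odds ratio 1.14, exact p = 0.624) passed in that set. The site was also counted in each replicate's own highest regions. Among the 33 highest, 14 had it in replicate 2 (42.4%, odds ratio 3.71, exact p = 4.2e-04 against the pooled background) and 6 in replicate 1 (18.2%, odds ratio 1.12, exact p = 0.814), and the direct test between the replicates did not pass (exact p = 0.0594). Among the 100 highest, a number chosen after the data were seen, 38% of replicate 2's regions and 15% of replicate 1's had TGATAA. The exact p between the 2 lists was 3.7e-04, with regions as units. The lists shared 10 of these 100 regions and 6 of the 33 highest, but both tests between replicates treated them as independent. Each list's own background was 17.7% and 17%.

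**Figure D4:**
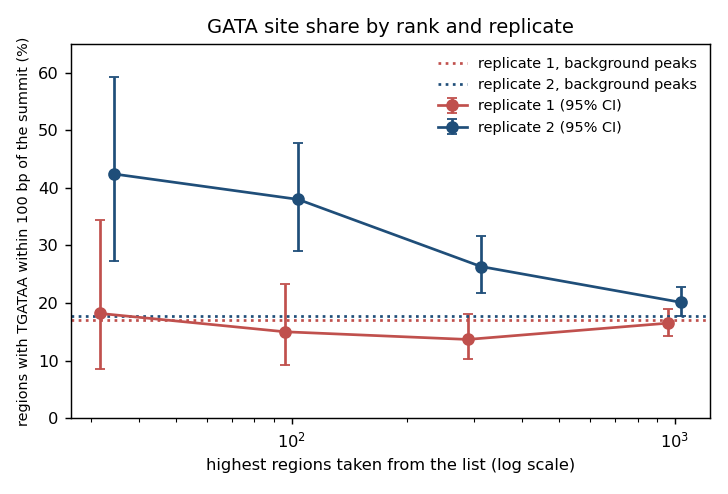
Share of regions with TGATAA within 100 bp of the summit (vertical, percent) among the highest regions of each replicate's list (horizontal, log scale), with 95% Wilson intervals; dotted lines are each list's background peaks. Replicate 2 runs from 42.4% at 33 regions to 20.1% at 1000, and replicate 1 lies between 13.7% and 18.2%.

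The gene lists asked whether hypodermal and other tissue genes had these regions in their promoter windows. Among the IDR regions 0 of 21 lists passed the Benjamini-Hochberg adjusted threshold of Fisher's exact test, and 3 had an unadjusted p under 0.05. Those 3 rested on 1 gene each. They were the hypodermal identity and seam cell regulators (elt-3, 1 of 11 genes, exact adjusted p = 0.133), the GATA factors (elt-3, 1 of 6, exact adjusted p = 0.133) and the cytosolic ribosomal proteins (rpl-3, 1 of 23, exact adjusted p = 0.184). For the replicated high-rank set 0 lists passed and 3 had an unadjusted p under 0.05, again with 1 gene each at an adjusted exact p of 0.252. These genes were nlp-33, an epidermal antimicrobial peptide gene, fat-6, an intestinal fatty acid desaturase gene, and rpl-3. The other 16 lists had 0 genes in either set. They were both cuticle collagen lists, epithelial structure, moulting, hedgehog-related genes, stress response, heterochronic genes, nuclear hormone receptors, glutathione S-transferases, cytochrome P450s, body wall muscle, pharynx, neurons, germline, histones and heat shock proteins. With replicate 2 alone in place of the IDR list, ribosomal proteins passed (rpl-1 and rpl-3, exact adjusted p = 0.012), and with replicate 1 alone required for the high-rank set, the GATA factors (exact adjusted p = 0.0011) and the hypodermal regulators (exact adjusted p = 0.0043) passed through the same genes, egl-27, elt-3 and elt-6. Of these, rpl-1 and elt-6 were named after their values were seen.

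The nearest start at any distance gave a further comparison with the hypodermal lists, chosen with its genes after the data were seen. The nearest protein-coding start belonged to 1 of the 7 hypodermal lists for 5 of 33 IDR regions (15.2%), against 2.55% of background peaks (exact p = 0.0014), namely at col-17, egl-27, sqt-2 and both elt-3 regions. Each of these 5 ranked beyond 1000 in 1 replicate, so that they were 5 of the 10 such IDR regions and 0 of the 23 in both replicates' 1000 highest. In the replicated high-rank set it did so for 8 of 68 (11.8%, exact p = 3.6e-04), at the collagen genes col-94, col-144, col-165 and rol-8, at dlg-1, at let-805, which encodes a transmembrane protein of hypodermal attachment structures, at nlp-33 and at lrp-1, a gene needed for moulting. The let-805 and lrp-1 starts were 7427 and 9901 bp from the summits. Taken singly, 2 of the 21 lists passed in the IDR set, the GATA factors and the hypodermal regulators, both through the elt-3 and egl-27 regions, and 0 passed in the replicated high-rank set (lowest exact adjusted p = 0.273).

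Chromosome X held 13 of the 33 IDR regions (39.4%, interval 24.7 to 56.3%) against 18% of background peaks (odds ratio 2.97, exact p = 0.0046), and 22 of the 68 high-rank regions (32.4%, odds ratio 2.18, exact p = 0.0040). The 13 included both elt-3 regions and the nearby meg-1 region, named after its value was seen. The test was not repeated without that locus alone, which was left out only together with the dense bins of chromosome I. With a single replicate's 33 highest regions in place of the IDR list, the odds ratio was 2.28 for replicate 2 (exact p = 0.037) and 1.46 for replicate 1 (exact p = 0.362). In the 16 IDR regions of highest signal value it was 5.87 (exact p = 6.6e-04). The high-rank odds ratio was 4.30 with 500 regions per list, 1.24 with 2000 and 0.922 to 1.16 when 1 replicate sufficed. Chromosome I held 11 IDR regions (33.3%) and 25 high-rank regions (36.8%) against 16.1% of the background, and its first 5 Mb alone, a limit set after the positions were seen, held 8 and 21 of them. Bins of 0.5 Mb that were dense in replicate 1's 1000 highest regions numbered 13, of which 12 lay on I and 1 at elt-3 on X, and they held 14 of the 33 IDR regions.

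**Figure D5:**
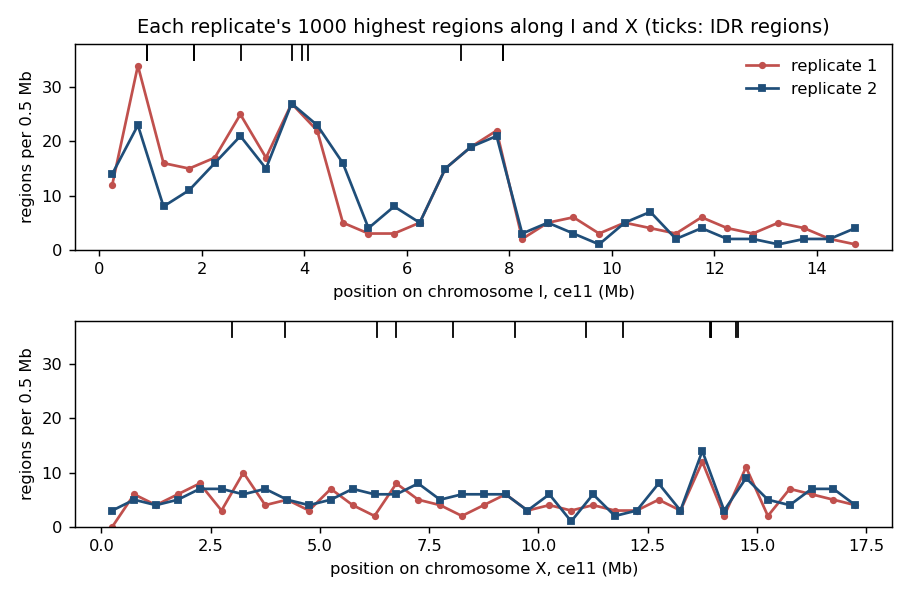
Number of each replicate's 1000 highest regions per 0.5 Mb (vertical) along chromosomes I and X (horizontal, Mb, ce11), with black ticks at the IDR summits. On I both replicates are high in the same stretches, reaching 34 in replicate 1 and 27 in replicate 2.

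Non-coding RNA genes lay within 200 bp of 1 of the 33 IDR summits (3.03%, exact p = 0.215) and of 4 of the 68 high-rank summits (5.88%, interval 2.31 to 14.2%), against 0.724% of background peaks (odds ratio 8.57, exact p = 0.0017 for the high-rank set). The 4 regions, named after the values were seen, lay at the snoRNA genes T03F7.8 and F59C6.15, at the snRNA gene R07E5.16, whose nearest protein-coding start was that of col-94, and within 200 bp of a pair of tRNA genes, in a region at 3035812 to 3036161 on X. The high-rank odds ratio was 3.08 and 2.70 when 1 replicate sufficed and 1.95 over the pooled 1000 highest, the last chosen after the data were seen. Within 500 bp the IDR set also passed (odds ratio 7.11, exact p = 0.0109).

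The ce10 lists gave 38 IDR regions, the 38 highest of the pooled ce10 list. Of the 33 ce11 IDR regions, 32 had a ce10 IDR region on the same chromosome with a signal value within 0.01.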

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

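Of 117 alternatives over 16 values, 88 left the result unchanged. Unchanged meant the same side of the threshold for tests, with the same direction where either value passed it, a share inside the first interval, or a count within 1.5 times. For both GATA results the count of 88 includes the median of 54 other orders of the bases of TGATAA. That median is a control, and its place among the unchanged values lends the GATA results no support. The settings outside the dense bins, over the pooled 1000 highest with no replicate required, and with the nearest gene at any distance were chosen after seeing the data. The cause of the changes below was not tested. The replicate overlap was 4.1% within 50 bp and 8.8% within 300 bp. The share of IDR regions in both replicates was 84.8% with 2000 regions per list, and 81.8 to 87.9% when a single replicate was required. The high-rank set numbered 33 with 500 regions, 169 with 2000, 41 within 50 bp, 43 outside the dense bins and 363 to 364 with 1 replicate. Each of these settings narrows or widens the rule that defines the set. For TGATAA in IDR regions the odds ratio was 2.25 for WGATAR, 2.72 for HGATAR and 1.12 to 3.71 with a single replicate's 33 highest. For the high-rank set it was 1.23 over the pooled 1000 highest, the other direction and past the threshold. The odds ratio for X was 1.46 to 2.28 with a single replicate's 33 highest regions in place of the IDR set, and 5.87 in the 16 IDR regions of highest signal value. In the high-rank set it was 4.30 with 500 regions, 1.24 with 2000 regions, 0.922 to 1.16 with 1 replicate and 0.928 with none required. Outside the dense bins the values were 4.79 and 3.75, but leaving these bins out removes all 11 IDR regions of chromosome I, so these values do not show a stronger X result. The high-rank promoter odds ratio was 0.494 with the 500 bp window, 0.547 outside the dense bins, 0.942 over the pooled 1000 highest and 0.887 to 0.938 with 1 replicate, none past the threshold. For non-coding RNA genes the IDR odds ratio was 7.11 within 500 bp, and the high-rank odds ratio was 2.70 to 3.08 with 1 replicate and 1.95 over the pooled 1000 highest, all past the threshold. The gene lists gave 0 to 1 calls with a single replicate's 33 highest regions in place of the IDR set, and 2 for the IDR set by nearest gene at any distance. The high-rank lists gave 0 to 2 with 1 replicate, 1 over the pooled 1000 highest and 0 by nearest gene at any distance. The read depth of the libraries is unknown, and 33 and 68 regions limit every share.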

Other observations

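The tests in this part were chosen after the result was seen, except those of region density around elt-3, of signal at unc-119 and of region density on the first 5 Mb of chromosome I, whose 5 Mb limit was itself set after the positions were seen. Genes named here outside the fixed rule were likewise chosen after their values were seen. Replicate 2's 100 highest regions included 38 with TGATAA, and outside the dense bins 28 of 63 had the site (44.4% against 18% of its background, odds ratio 3.65, exact p = 1.2e-06), while replicate 1 had 8 of 53 there (15.1% against 17.1%, exact p = 0.855). Of the 38 regions, 7 were IDR regions, 7 ranked in replicate 1's 1000 highest, 16 ranked lower there and 15 had no replicate 1 summit within 150 bp. The regions with the site in replicate 2 were nearest to, among others, nlp-24, an epidermal antimicrobial peptide gene (rank 33), mua-3, a hypodermal attachment gene (rank 99), bcat-1 (rank 12), cdo-1 (rank 37), acly-1 (rank 52) and egl-15 (rank 61). The nearest start belonged to a hypodermal list for 9 of replicate 2's 100 highest regions (9.0% against 2.41%, odds ratio 4.01, exact p = 7.8e-04), at col-17, col-47, col-90, elt-3, grl-16, mua-3, nlp-24, ptc-3 and ptr-11. For replicate 1 it did so for 7 of 100 (7.0% against 2.39%, odds ratio 3.08, exact p = 0.0107), at col-56, dpy-14, egl-27, elt-3, noah-2, rol-8 and sqt-2, so that elt-3 was the gene in both. In replicate 2 a hypodermal nearest gene was found for 3 of the 38 regions with TGATAA (7.89%) and for 6 of the 62 without it (9.68%).

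In the pooled list's 1000 highest regions, 19.6% had TGATAA against 16.6% of the background. Of 2080 6-mers TGATAA ranked 382nd by p (exact adjusted p = 0.0874), with enriched and depleted 6-mers ranked together. At an adjusted exact p under 0.05, 158 were enriched and 120 depleted. The lowest p belonged to AAAATT, at 36.6% against 55.3%, and the median GC content was 42.3% against 38.3%.

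IDR and high-rank regions together lay nearest to a gene of the 7 hypodermal lists in 13 of 78 cases (16.7%, odds ratio 7.65, exact p = 1.1e-07), and in 11 of 76 without elt-3 (odds ratio 6.53). For summits outside coding exons the odds ratio was 7.03 (8 of 54, exact p = 5.0e-05), so summits within coding exons were not the whole of it. Over all 78 regions, with background matched on GC content, it was 7.06. Only the summit base was classed, so signal over transcribed genes cannot be excluded as the cause. Of the 8 regions, only those at col-94 and rol-8 did not overlap the hypodermal gene. The summits at egl-27 and dlg-1 and both elt-3 summits lay in introns of those genes. The regions at col-17 and col-144 reached into theirs. A candidate explanation is binding of ELT-3 through GATA sites, but 2 of the 13 regions had TGATAA (15.4%, interval 4.33 to 42.2%, against 16.6%), too few to decide. Open chromatin or high transcription at hypodermal genes was not tested and stays open. Of the 21 lists taken singly, both collagen lists passed (exact adjusted p = 0.0146 each), on 4 regions for the col-numbered genes and 2 for those with mutant names. None of these summits lay in the promoter window of a collagen gene, and the col-94 summit lay at the snRNA gene R07E5.16. The GATA factors and hypodermal regulators passed through the same 3 regions, 2 of them at elt-3, the gene that the transgene carries.

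Around elt-3, 3 IDR regions lay within 40 kb, 2 in elt-3 and 1 in a coding exon of meg-1, named after its value was seen. Extra copies of the elt-3 region in the transgene may add reads there, and the count of 27 other pooled-list regions stood at the 99.2nd percentile of 40 kb windows. Each replicate had 7 of its 1000 highest regions in the window. Extra copies of the worm's own unc-119 relative to the control are argued against. Its highest pooled signal value stood at the 28.7th percentile of 10 kb windows. Its region counts in 40 kb stood at the 74.8th (replicate 1), 37.9th (replicate 2) and 85.6th (pooled). However, its highest region stood at the 93.5th percentile of replicate 1's list and the 7.74th of replicate 2's. Copies that the control also carried would not show in these values, so the values cannot decide on them. A marker sequence that does not map to the worm's gene and binding of ELT-3 to its own gene apart from copy number were not tested and stay open.

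The 13 dense bins chosen in replicate 1, of which 12 covered 0 to 4.5 Mb and 6.5 to 8 Mb of I and 1 lay at elt-3 on X, held a mean of 17.5 ± 5.39 (SD over bins) of replicate 2's 1000 highest regions, against 4.13 ± 2.44 in the 184 other bins. A copy number or mapping difference against the control may be the source on I, as regions ranked beyond 1000 were 1.57 times denser on its first 5 Mb than elsewhere. For X against the autosomes that ratio was 1.02, which argues against such a difference over the whole of X. A ratio for the whole chromosome cannot exclude local extra copies, such as may lie around elt-3. GC content and coding density are argued against, since the dense bins held 4.11 times as many as the 156 other bins of like composition. Repeats are argued against for the 78 IDR and high-rank regions together. Of these, 3 were soft-masked over 50% or more of their bases (odds ratio 0.253, exact p = 0.0075). Only 31 of the 78 lay in the dense bins, and the other high regions of those bins were not tested for repeats. No biological explanation was tested.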
